A study of Mus musculus with 8 samples.

How the data were processed

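Small RNA libraries of 4 neonatal and 4 adult mouse samples were compared. Per the labels' protocols, spleens were made into cell suspensions, CD8+ T cells were enriched with magnetic beads against CD8a, total RNA was extracted with Trizol and an additional chloroform step, and libraries were built with the NEBNext small RNA kit and size selected for short inserts. Such kits ligate adapters with sequence preferences, so levels of different miRNAs in a library are not directly comparable, while the same miRNA can be compared between libraries. The labels do not say whether the samples of a group came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical. Magnetic enrichment leaves some other cells, and miRNA lists of such cells were therefore measured in both groups.

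The authors deposited 1 table of estimated counts per mature miRNA and precursor, not normalized. Reads were placed on the mouse build mm10, per the submitters' processing notes. The aligner, the counter and the miRNA annotation release are not given in the sources used here. Of the non-zero estimated counts as deposited, 71.4% were whole within 0.001, and most others were simple fractions, as when a read that maps to several places is shared among them. The table had 2128 entries for 1978 mature miRNAs on 1234 precursors, with 83 mature miRNAs on more than 1 precursor and 1036 with a count. All columns of values matched a sample by name. Values of a mature miRNA were summed over its precursors and rounded to whole numbers. Sharing of reads means that near-identical miRNAs, such as those of the let-7 family or the Sfmbt2 cluster, are not fully separated.

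Total counts were 1281032 to 2606630 per library, so that 1 count equals 0.384 to 0.781 CPM, and 3 counts, the limit that a count of 0 allows, 1.15 to 2.34 CPM before TMM scaling. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 19.1 to 450), so none was treated as a copy of another, although a second library of the same RNA could differ as much. The first principal component of log CPM held 77.2% of the variance and separated the ages.

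miRNAs were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 375. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling and robust dispersion estimates (biological coefficient of variation 21.4%), with age group as the only term, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors were derived from the fold change and its F value. A total of 20 lists of miRNAs (families, clusters, resting and activated T cells, and miRNAs of other cell types), the tests and the rule for naming miRNAs were fixed before the data were examined. In these lists 125 miRNAs were tested and 101 changed, both over all miRNAs and when adjusted over the lists alone. Lists with at least 3 tested members (17) were compared with all other miRNAs by camera in limma 3.58.1 with a preset correlation of 0.01 between members. No call held with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether the members move on balance in the same direction without comparing them with other miRNAs, called 16. The named miRNAs were the 10 with the largest positive and negative changes among those past the threshold with at least 100 CPM in either group and no overlap between groups, the 5 most abundant, and in each list the member with the smallest p and the most abundant one. Other list members are named as examples, and were chosen after their values were seen.

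Arm ratios were log2((5p count + 0.5)/(3p count + 0.5)) for hairpins with both arms past the filter, tested with limma with a trend on abundance. Shares of counts were compared by exact permutation tests over all ways of dividing the 8 libraries. Hairpin positions were taken from the RefSeq gene table of the same assembly and were the same in GENCODE for all 59 hairpins of the named miRNAs, and host genes came from GENCODE. GC content was computed on the side of the hairpin (5p or 3p) that holds the mature miRNA, from the hairpin's end to its midpoint. Where the name gives no arm, the whole hairpin was used. Values were averaged over precursors, and the sequenced insert itself was not used. GC content was found for 372 of the 375 tested (99.2%).

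Both groups carry replicate numbers 1 to 4 in the labels, which do not say what a number stands for. Deviations from the group means correlated between same-numbered neonatal and adult libraries at r = 0.256 to 0.415, above 0.1 in all 4 pairs, so the numbers were treated as pairing the samples from this check alone, and a fit with the number as a block was an alternative. Unlike-numbered libraries reached r = 0.482, and 3 of 4 adult libraries correlated best with their own number. Unlike-numbered libraries correlated positively where both numbers were odd or both even, and negatively otherwise. The second principal component (11.4% of the variance) was positive for libraries 1 and 3 and negative for 2 and 4 in both ages. The check therefore cannot separate 4 pairs from a split into odd and even numbers. Further alternatives were RLE and library-total scaling, other filters, DESeq2 1.42.0 and limma-voom, each library left out, abundant or other-cell miRNAs left out, an offset per library that removes the dependence on GC content, the largest precursor value in place of the sum, and fits of the libraries numbered 1 and 3 or 2 and 4 alone.

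On counts simulated for the comparison of neonatal with adult libraries from the means, totals and dispersions of the 1036 detected miRNAs, with 200 of them changed, 372 were tested. Of the changed ones tested, 27 of 34 at 2-fold and 46 of 46 at 4-fold were recovered in the right direction, with 1 false call among 74. With nothing changed, 0 of 377 were called. On simulated arm ratios, 20 of 20 hairpins changed 4-fold were recovered with 1 false call among 82 tested. The 200 changes were as often higher as lower, and the simulated libraries were independent. These simulations therefore do not cover a general shift between the groups or links between libraries. The 4-fold arm change is larger than most arm shifts found in the data.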

Results

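Small RNA was sequenced from splenic CD8+ T cells, the lymphocytes that kill infected and transformed cells, of C57BL/6 mice, an inbred laboratory strain. Libraries came from neonatal mice aged 5 to 7 days (n = 4) and from adult mice aged 12 weeks (n = 4). The reads of mature microRNAs (miRNAs), the short RNAs that repress target messenger RNAs, had been counted. The comparison of the age groups asked which miRNAs differ between neonatal and adult CD8+ T cells. Total counts were 1454421, 2116003, 1767997 and 2416060 in neonatal libraries 1 to 4, and 1281032, 1813383, 2606630 and 2454348 in adult libraries 1 to 4. A library held a count for 608 to 787 miRNAs. Levels are given below as depth-scaled counts (CPM) after TMM scaling, which sets libraries to a common level by their trimmed mean ratio, as mean ± SD of 4 libraries. Fold changes are neonatal over adult, on the log2 scale, with their standard error (SE).

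Among miRNAs with at least 100 CPM in either group, the sharpest falls in neonatal cells were those of miR-29b-3p, miR-29a-3p, miR-101a-3p, miR-125a-5p and miR-146a-5p. miR-29a-3p, known to restrain interferon-gamma production, stood at 884 ± 368 CPM in neonatal and 9456 ± 1145 CPM in adult libraries, and miR-101a-3p at 607 ± 256 and 6962 ± 1705 CPM. miR-146a-5p, a brake on NF-kB signalling, stood at 1600 ± 237 and 11650 ± 506 CPM. The largest rise at this level was that of miR-298-5p, from 95.0 ± 15.9 CPM in adult to 996 ± 70.6 CPM in neonatal libraries, followed by miR-351-5p, miR-148a-3p and miR-130b-5p. All of these had no overlap between the 4 neonatal and 4 adult libraries, which was a condition for naming them.

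Of 375 miRNAs tested, 237 (63.2%) changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 109 higher and 128 lower in neonatal libraries. The change was at least 2-fold for 83 of the higher and 84 of the lower ones. Neonatal and adult libraries did not overlap for 207 of the 237. Among the strongest falls at 100 CPM or more, the log2 fold change was -3.64 ± 0.25 (SE) for miR-29b-3p, -3.52 ± 0.29 for miR-101a-3p, -3.42 ± 0.26 for miR-29a-3p, -3.36 ± 0.19 for miR-125a-5p and -2.86 ± 0.15 for miR-146a-5p. Their adjusted p by edgeR ranged from 1.61e-08 for miR-146a-5p to 8.27e-07 for miR-101a-3p. Further falls were those of miR-1843a-5p (-2.65), miR-504-5p (-2.57), let-7b-5p (-2.52), miR-1843a-3p (-2.44) and miR-200a-3p (-2.17). Among the rises at this level, miR-298-5p changed by 3.39 ± 0.16, miR-351-5p by 2.81 ± 0.24, miR-148a-3p by 2.42 ± 0.17 and miR-130b-5p by 2.39 ± 0.19. Smaller ones were those of miR-122-5p (2.08), miR-486a-5p (1.84), miR-486b-5p (1.82), miR-363-5p (1.68), miR-183-5p (1.60) and miR-501-3p (1.5). miR-486a-5p and miR-486b-5p share a sequence, so their reads cannot be told apart.

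**Figure D1:**
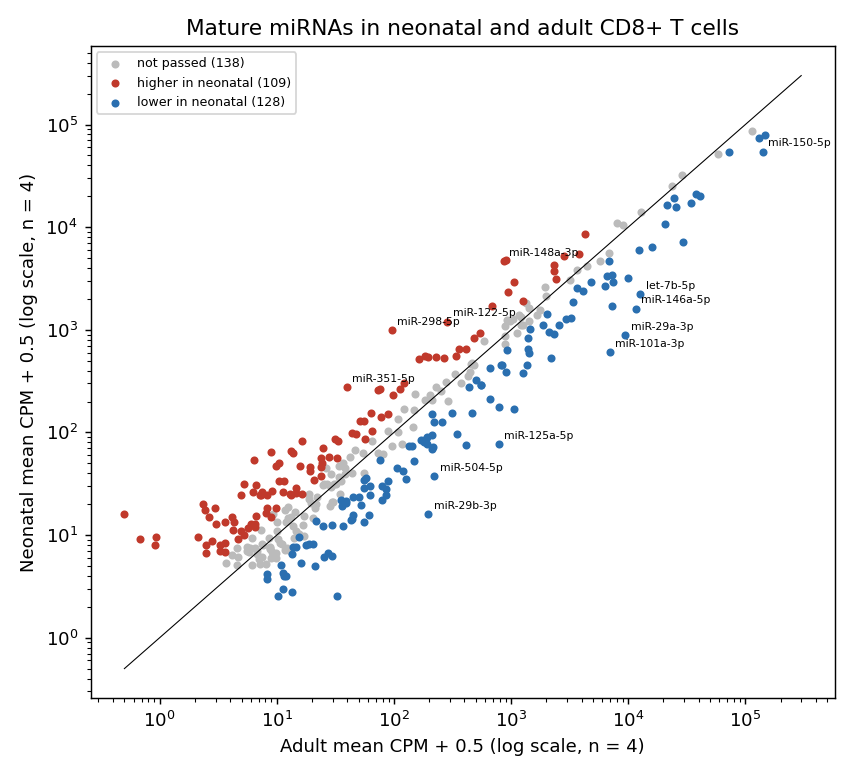
Mean level of each of the 375 tested miRNAs in adult (x axis) and neonatal (y axis) libraries, as TMM-scaled CPM plus 0.5 on log axes, with n = 4 per group and the line of equal levels. Red points were higher (109) and blue points lower (128) in neonatal libraries by edgeR's test, and grey points (138) did not pass.

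These counts depend on how libraries were set to a common level. TMM factors were 1.16 to 1.3 in neonatal and 0.788 to 0.812 in adult libraries, and scaling by library totals moved all log2 fold changes up by 0.626 on average. With totals 186 miRNAs were higher and 68 lower, so that 73.2% of the changed miRNAs were higher in place of 46.0%. Every fold change below is relative to the TMM scale. The fold change also followed GC content of the hairpin side across 372 miRNAs (Pearson r = 0.232, Spearman rho = 0.260). The permutation p was 0.0001 for both, the smallest that 10000 permutations can give, and miRNAs are not independent replicates. The median fold change ran from -0.74 in the fifth of miRNAs lowest in GC to 0.41 in the highest.

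The genes of these miRNAs lie apart in the genome (mm10). miR-29a and one copy of miR-29b are intergenic neighbours on chromosome 6 (31062660 to 31062747 and 31063023 to 31063093), and the other miR-29b copy lies in an exon of the noncoding gene A330023F24Rik (chromosome 1, 195037040 to 195037120). miR-101a lies in an exon of the noncoding gene E130102H24Rik (chromosome 4, 101346945 to 101347027), and miR-125a in an exon of the protein-coding gene Spaca6 (chromosome 17, 17830812 to 17830879). miR-146a (chromosome 11, 43374397 to 43374461), miR-148a (chromosome 6, 51269812 to 51269910), miR-298 (chromosome 2, 174267504 to 174267585) and miR-351 (chromosome X, 53053255 to 53053353) are intergenic. miR-130b lies in an intron of 2610318N02Rik (chromosome 16, 17124061 to 17124142). miR-1843a lies in an intron of Dcaf5 and overlaps the small Cajal body RNA Scarna3b on the same strand (chromosome 12, 80391613 to 80391677), so reads of either may be counted as the other.

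**Figure D2:**
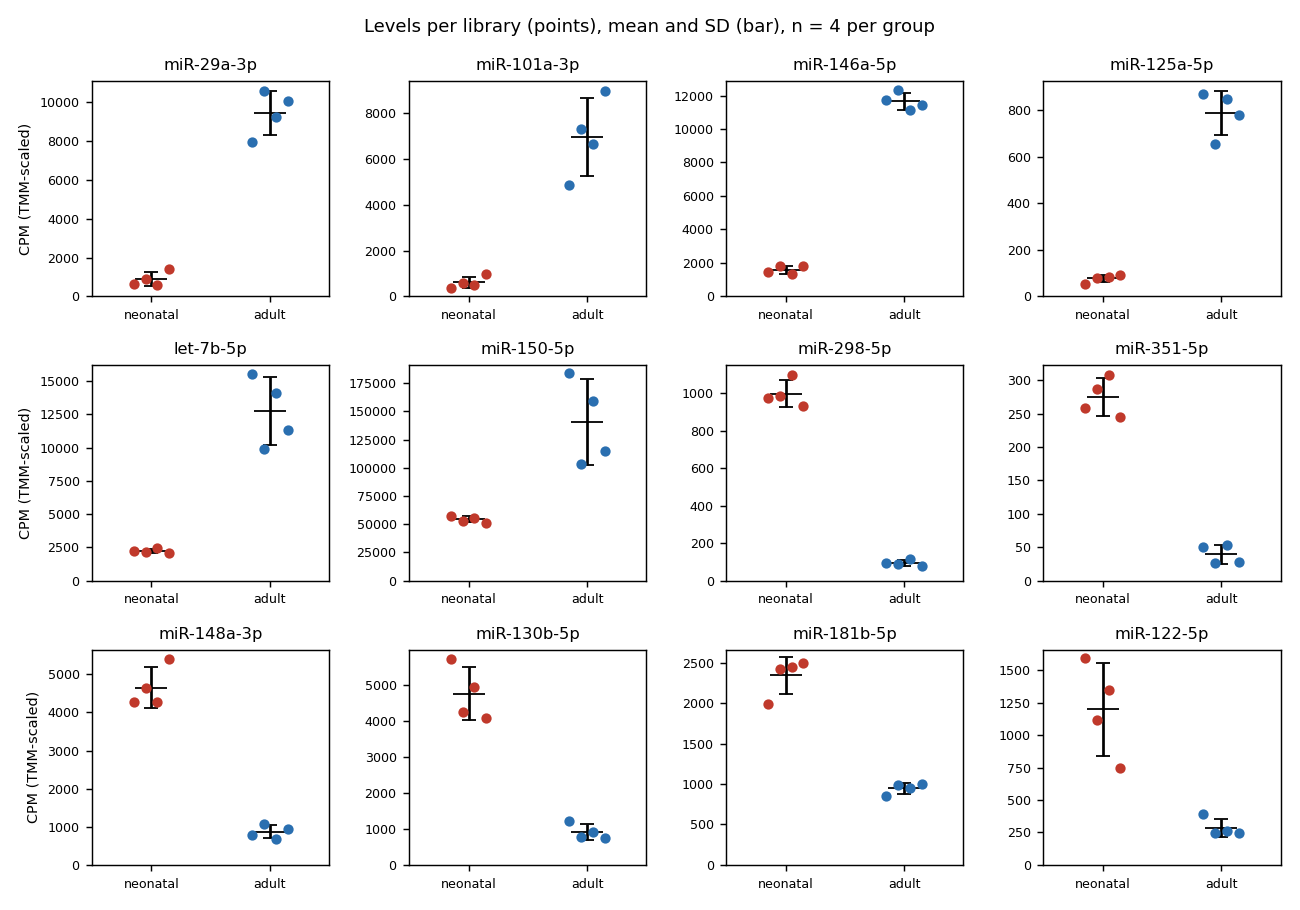
TMM-scaled CPM of 12 miRNAs in each neonatal (red) and adult (blue) library, with the mean (horizontal bar) and SD (error bar) of 4 libraries per group and axes from 0. miR-298-5p lay at 996 ± 70.6 CPM in neonatal and 95.0 ± 15.9 CPM in adult libraries, and miR-29a-3p at 884 ± 368 and 9456 ± 1145 CPM.

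The let-7 family, known for holding back proliferation genes, was among the most abundant groups. Of the 9 tested members on its list 7 fell, the count adjusted over the list alone being 7 as well. let-7b-5p fell from 12730 ± 2554 to 2216 ± 153 CPM and let-7c-5p from 29300 ± 4818 to 7138 ± 766 CPM, a log2 fold change of -2.04 ± 0.15. Falls were smaller for let-7g-5p (-0.89 ± 0.14), let-7f-5p (-0.82 ± 0.14), let-7e-5p, let-7a-5p (-0.44 ± 0.12) and let-7d-5p (-0.38 ± 0.13). let-7i-5p (0.08 ± 0.24) and miR-98-5p (0.25 ± 0.16) did not pass, nor did let-7j (0.44 ± 0.22, edgeR's adjusted p = 0.105), which is not on the list. miR-98-5p passed as higher with an offset for GC content (0.37 ± 0.13, edgeR's adjusted p = 0.0264). With an offset for GC content let-7a-5p and let-7d-5p went to -0.11 ± 0.13 and -0.06 ± 0.14 and lost their calls (edgeR's adjusted p of 0.474 and 0.745), and let-7a-5p also did without a filter (0.0668), without adult library 3 (0.0511) and without neonatal library 2 (0.0632). With library totals let-7a-5p and let-7d-5p turned to 0.20 and 0.25, and the family had 2 members lower and 2 higher. The family stood below other miRNAs by camera (adjusted p = 0.0438), a call lost with an estimated correlation (adjusted p = 0.239 with an estimated correlation). The listed let-7 miRNAs took 32.2% ± 0.621 of neonatal and 35.2% ± 2.18 of adult counts, a difference that did not pass (exact permutation test, two-sided, p = 0.0571, n = 4 per group).

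All 3 members of the miR-29 family fell (3 adjusted over the list alone), including miR-29c-3p from 31.9 ± 5.77 to 2.05 ± 0.896 CPM. The neonatal level of miR-29c-3p rests on 2 to 8 counts per library, near the floor of 3 counts, so the size of its fall is imprecise. The family's median log2 fold change was -3.64 (camera adjusted p = 0.000237, adjusted p = 0.239 with an estimated correlation). Of 6 miRNAs linked to resting T cells, 5 fell (5 adjusted over the list alone, and 4 lower and 1 higher with library totals; camera adjusted p = 0.0438, adjusted p = 0.239 with an estimated correlation). miR-150-5p, abundant in mature lymphocytes, went from 140500 ± 37920 in adult to 54310 ± 2743 CPM in neonatal libraries (-1.37 ± 0.18), and miR-139-5p from 7329 ± 555 to 1694 ± 206 CPM (-2.11 ± 0.14). miR-26a-5p (-1.02), miR-26b-5p (-1.3) and miR-342-3p (-0.72) fell too. miR-342-5p stood at 0.45 ± 0.21 and did not pass by edgeR (adjusted p = 0.0833, and 0.00217 with the replicate number as a block). The camera calls of the let-7 and resting lists were lost without adult library 3 or any neonatal library, at adjusted p of 0.0552 to 0.0796, and also with RLE scaling (0.0552 for both), library totals (0.182 and 0.0937), at least 10 CPM in 4 libraries (0.0994 and 0.098) and without the 10 most abundant miRNAs (0.0661 and 0.148). The let-7 call was further lost without the erythroid, myeloid and endothelial miRNAs (0.0762), in libraries 1 and 3 alone (0.062) and with an offset for GC content (0.0746, and 0.0861 with the replicate number as a block), which moved the family's median from -0.82 to -0.34. The resting call was further lost in libraries 2 and 4 alone (0.0501).

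**Figure D3:**
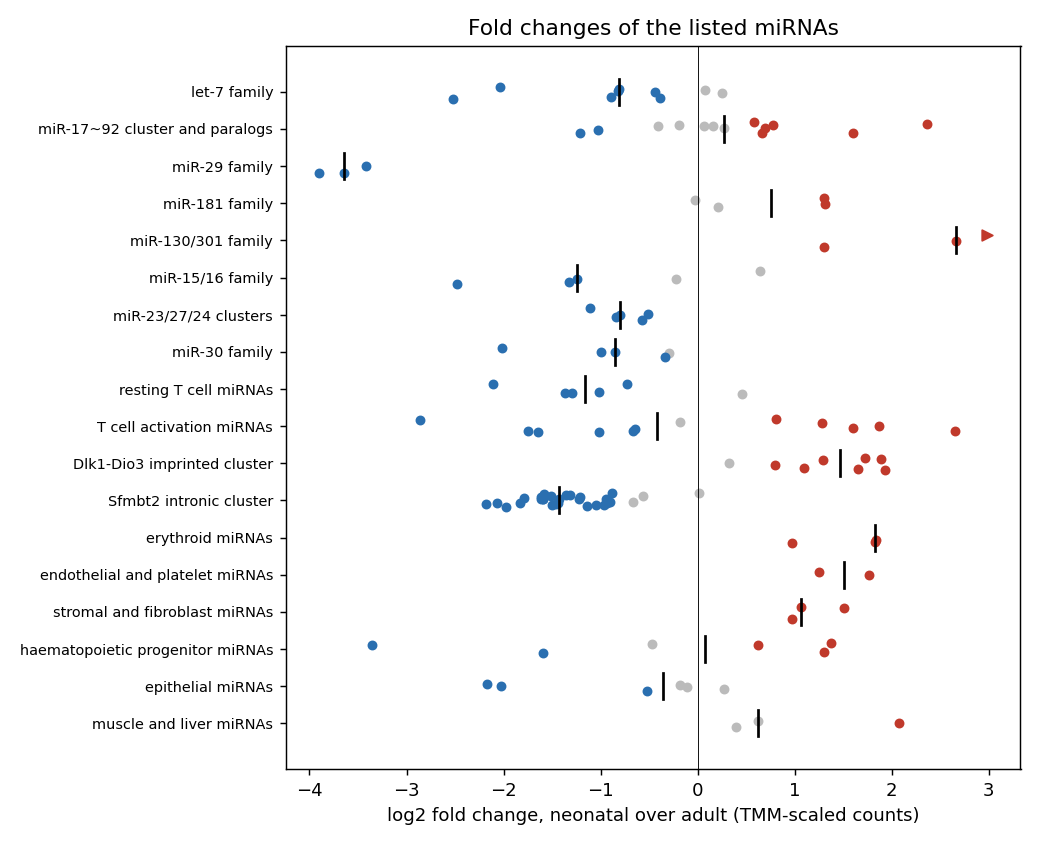
Log2 fold change (neonatal over adult, TMM-scaled counts, x axis) of each tested member of 18 lists, with a black bar at each list's median. Red and blue points passed edgeR's test as higher and lower, and grey points did not. The triangle marks miR-301b-3p at its lower bound. All 3 miR-29 members lie at -3.42 or below. With library totals all values move up by about 0.626, and let-7a-5p, let-7d-5p, miR-23b-3p, miR-24-3p, miR-30c-5p and miR-203-3p, blue here, turn above 0.

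Of 12 miRNAs that follow T cell activation, 5 rose and 6 fell (5 and 6 adjusted over the list alone), with library totals 5 rose and 3 fell, and camera gave no call (adjusted p = 0.648). miR-155-5p, needed for effector responses of CD8+ T cells, fell from 1266 ± 172 to 376 ± 27 CPM (-1.75 ± 0.15). miR-146a-5p, miR-221-3p (-1.64), miR-222-3p (-1.01), miR-146b-5p and miR-96-5p fell as well. miR-210-3p, induced by low oxygen, rose by 2.65 ± 0.27, and miR-31-5p (1.87), miR-183-5p (1.60), miR-132-3p (1.28) and miR-182-5p (0.81) also rose. miR-21a-5p, at 51330 ± 15130 and 58380 ± 18760 CPM, did not pass (-0.19 ± 0.24), and its sign turned with library totals.

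In the miR-181 family, miR-181a is the member known to set T cell receptor sensitivity in thymocytes. Of the 4 miR-181 members, miR-181b-5p (1.31 ± 0.14) and miR-181d-5p (1.3 ± 0.21) rose (2 adjusted over the list alone). miR-181a-5p (0.21 ± 0.14) and miR-181c-5p (-0.03 ± 0.20) did not pass, while with library totals all 4 were higher, and miR-181a-5p also passed with RLE scaling and with DESeq2 (adjusted p of 0.0493 and 0.0286). The 3 tested members of the miR-130 and miR-301 family rose (3 adjusted over the list alone). miR-301b-3p had no count in any adult library and 15.7 ± 3.83 CPM in neonatal libraries, at least 7.9-fold higher against a floor of 3 counts per library. miR-301a-3p rose by 2.66 ± 0.43 and miR-130b-3p by 1.3 ± 0.21, and the family's median, with miR-301b-3p at its bound, was 2.66. The family's camera call (adjusted p = 0.0438) was lost with the replicate number as a block (adjusted p = 0.0646), without adult library 3 (0.0601) or neonatal library 4 (0.0667), with library totals (0.0584), at least 10 CPM in 4 libraries (0.0562) and the GC offset (0.0714, and 0.0905 with the block), in libraries 1 and 3 (0.0715) or 2 and 4 alone (0.0536), and at adjusted p = 0.255 with an estimated correlation.

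In the miR-17~92 cluster and its paralogs, known drivers of lymphocyte proliferation, 6 of 13 members rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.274), and 9 were higher and 1 lower with library totals. miR-18b-5p (2.36 ± 0.36), miR-18a-5p (1.60 ± 0.31) and miR-17-5p (0.58 ± 0.15) rose, and miR-19b-3p (-1.22 ± 0.21) and miR-19a-3p (-1.03 ± 0.33) fell. With the GC offset miR-20b-5p also passed as higher (0.61, edgeR's adjusted p = 0.00178) and miR-25-3p as lower (-0.30, edgeR's adjusted p = 0.026). miR-92a-3p, among the 5 most abundant miRNAs, stood at 86240 ± 17350 in neonatal and 114600 ± 28600 CPM in adult libraries. Its change of -0.41 ± 0.19 did not pass by edgeR (adjusted p = 0.0853) but did with the replicate number as a block (adjusted p = 0.00574), and turned to 0.23 with library totals. The 5 members of the miR-23/27/24 clusters fell (5 adjusted over the list alone; camera adjusted p = 0.17), led by miR-27a-3p (-1.11 ± 0.22) and with miR-27b-3p at -0.84 ± 0.19. With library totals only miR-27a-3p passed, and miR-23b-3p and miR-24-3p turned above 0. miR-23b-3p lost its call with the GC offset (-0.21 ± 0.12, edgeR's adjusted p = 0.14). Of the miR-30 family 4 of 5 fell (4 adjusted over the list alone; camera adjusted p = 0.17), among them miR-30b-5p (-2.02 ± 0.20) and miR-30d-5p (-0.998 ± 0.163). With library totals 2 of them were lower and 1 higher. The higher one, miR-30c-5p, turned from -0.34 to 0.29, a call in the other direction (edgeR's adjusted p = 0.0328). It went to 0.03 ± 0.10 with the GC offset and lost its call (edgeR's adjusted p = 0.807). Of the miR-15/16 family, which slows the cell cycle, 3 of 5 fell (3 adjusted over the list alone; camera adjusted p = 0.17), including miR-16-5p (-1.24 ± 0.15), miR-15b-5p (-1.32 ± 0.19) and miR-195a-5p. miR-15a-5p (-0.22, above 0 with totals) and miR-322-5p (0.64) did not pass. Without a filter on low counts camera did call the miR-23/27/24 (adjusted p = 0.0156), miR-30 and miR-15/16 lists (0.0132 for both). It then also called the miR-181 list (0.0279).

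Of 29 tested miRNAs of the Sfmbt2 intronic cluster (chromosome 2), a rodent array of near-identical hairpins, 26 fell and none rose (26 adjusted over the list alone), with a median of -1.43. The span of 10466944 to 10518279 was taken from 27 of them. This list had camera's smallest adjusted p (5.82e-06, adjusted p = 0.324 with an estimated correlation). miR-467a-5p fell from 1367 ± 127 to 456 ± 86.6 CPM (-1.58 ± 0.16). Reads of these hairpins are shared between copies, so single members are uncertain, and with library totals 18 were lower and miR-669c-5p higher. With the GC offset miR-466b-3p, miR-466c-3p and miR-466e-3p lost their calls (edgeR's adjusted p of 0.19, 0.246 and 0.149). miR-669c-5p then passed as higher (0.43 ± 0.17, edgeR's adjusted p = 0.0414), and the list kept its camera call. Of 8 tested miRNAs of the Dlk1-Dio3 cluster (chromosome 12), 7 rose (7 adjusted over the list alone) without a camera call (adjusted p = 0.0946, but 0.0378 with limma-voom and 0.0202 without a filter, both called), with miR-543-3p at 1.65 ± 0.32 and miR-369-3p at 0.80 ± 0.20. The H19 and Igf2 miRNAs had too few counts to test.

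miRNAs typical of other cells did not move as one, and camera called none of their lists with at least 3 tested members, although it called the erythroid list without a filter (adjusted p = 0.0156) and in libraries 1 and 3 alone (0.0449). The erythroid, endothelial and stromal miRNAs with enough counts to test were higher in neonatal libraries. The red cell miRNAs miR-451a (45.9 ± 6.84 against 23.5 ± 4.52 CPM) and miR-486a-5p (257 ± 103 against 72.6 ± 24.5 CPM) rose, as did miR-486b-5p, so that all 3 tested erythroid miRNAs were higher (3 adjusted over the list alone; camera adjusted p = 0.155). Erythroid and myeloid miRNAs together took 0.0741% ± 0.0300 of neonatal and 0.0146% ± 0.00436 of adult counts (exact permutation test, two-sided, p = 0.0286, the smallest possible with n = 4 per group). An exact sign-flip test within same-numbered pairs gave p = 0.125, the smallest that 4 pairs allow. Both tested endothelial miRNAs rose (2 adjusted over the list alone), miR-126a-3p by 1.25 ± 0.20 and miR-126a-5p by 1.77 ± 0.41. The 3 stromal ones rose (3 adjusted over the list alone; camera adjusted p = 0.17), with miR-10b-5p at 1.51 ± 0.24, miR-143-3p at 1.07 and miR-199a-3p at 0.97. The 5 other stromal miRNAs had at most 12 counts in any library, and without a filter the median of this list fell from 1.07 to 0.36 (camera adjusted p = 0.357). Of the muscle and liver list, miR-122-5p, the main liver miRNA, rose from 286 ± 70.4 to 1200 ± 360 CPM (1 adjusted over the list alone), while miR-1a-3p (0.39) and miR-133a-3p (0.62) did not pass (2 of the 3 higher with library totals; camera adjusted p = 0.274). No myeloid miRNA passed the count filter, and miR-223-3p had 1 to 20 counts per library.

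Of 6 tested epithelial miRNAs, 3 fell and none rose (3 adjusted over the list alone; camera adjusted p = 0.391). miR-200a-3p fell from 789 ± 191 to 175 ± 73.8 CPM, miR-141-3p by -2.03 ± 0.54 and miR-203-3p by -0.52 ± 0.18, which turned to 0.10 with library totals. miR-200b-3p, at 1546 ± 100 and 1758 ± 119 CPM, did not pass (-0.18 ± 0.13), but with library totals it passed as higher (0.45, edgeR's adjusted p = 0.00503), and the balance of the list turned to 3 higher and 2 lower. Of 6 miRNAs of blood progenitors, miR-125b-5p (1.37 ± 0.28), miR-100-5p (1.3 ± 0.20) and miR-99a-5p (0.62 ± 0.20) rose, and miR-125a-5p and miR-99b-5p (-1.59 ± 0.21) fell (3 and 2 adjusted over the list alone). This list's median was 0.08 and its mean -0.35, and camera, which pointed down, gave no call (adjusted p = 0.535). miR-10a-5p (-0.47, above 0 with totals) did not pass in the main fit but did with the replicate number as a block (edgeR's adjusted p of 0.129 and 0.0471).

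The ratio between the 5p and 3p arms, the strands released from the same hairpin, asked whether arms of a hairpin moved together, and does not depend on scaling. It changed for 36 of 82 hairpins by limma's moderated test (Benjamini-Hochberg adjusted p under 0.05), 17 toward the 5p and 19 toward the 3p arm. miR-150 showed the smallest p. Its log2 ratio of 5p over 3p counts was 4.38 ± 0.11 (SD) in neonatal and 6.16 ± 0.18 in adult libraries, a difference of -1.78 ± 0.13 (SE, limma adjusted p = 1.6e-06). miR-139 (-1.85), miR-30b (-1.56) and miR-15b (-1.18) also shifted toward the 3p arm. miR-342 (1.15 ± 0.14), miR-17 (1.09 ± 0.17), miR-27a (1.36 ± 0.23) and miR-200a (1.79 ± 0.30) shifted toward the 5p arm. In 15 of the 36 the fold changes of the arms had opposite signs, a count that does depend on scaling. With library totals 9 of these and 6 others had opposite signs. These are signs of estimates, not tests of each arm. Among the 15 only miR-17 had both arms past edgeR's threshold (adjusted p of 0.00432 for 5p and 0.0419 for 3p). In the others an arm did not pass, such as miR-28a-5p (0.012) and miR-32-3p (0.033). Counts of the minor arm were often low, and miR-301b, whose 3p arm had no count in adults, rests on the pseudocount.

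**Figure D4:**
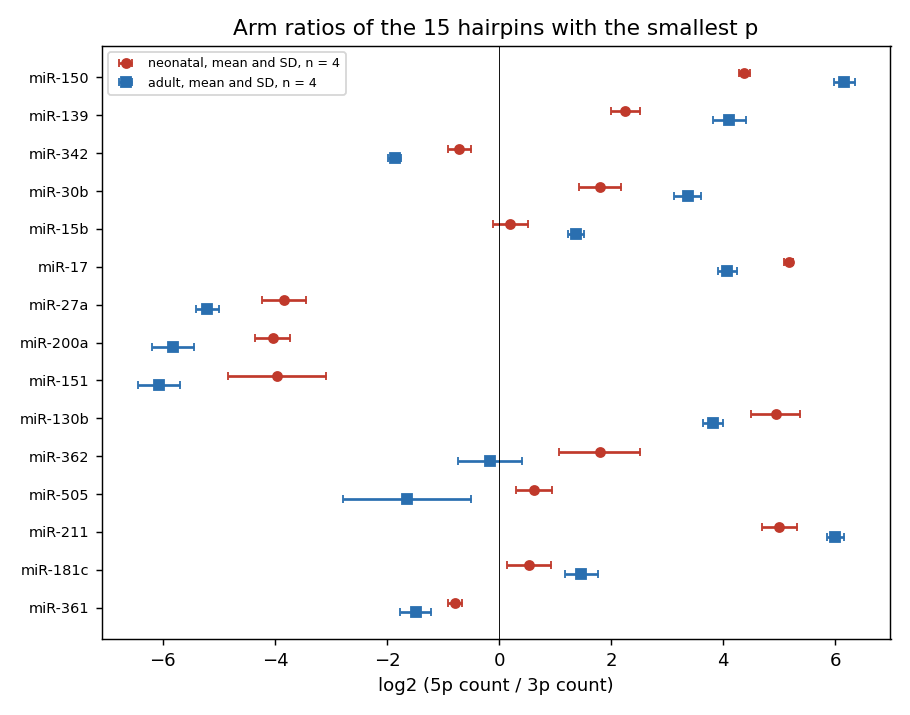
Log2 ratio of 5p to 3p counts (x axis) of the 15 hairpins with the smallest p by limma, as mean and SD of 4 neonatal (red circles) and 4 adult (blue squares) libraries. miR-150 lies at 4.38 ± 0.11 in neonatal and 6.16 ± 0.18 in adult libraries.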

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

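The tests of scaling and of other cells were chosen only after the result was seen, although the fit with library totals and the erythroid and myeloid share were themselves planned, and those on GC content after the data but before their own results were seen.

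A library stood apart from the other 3 of its group in 4 of 98 groups of values examined, where chance gives about 1 in 20. miR-122-5p was at 390 CPM in adult library 1 against 245 to 262 CPM in the other adult libraries. In neonatal library 1, miR-181b-5p was at 2000 CPM against 2430 to 2510, miR-1843a-3p at 67.2 CPM against 77.6 to 79.7, and miR-369-3p at 67.2 CPM against 51.8 to 52.9. All 4 values lay on their own side of the other age group's range.

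The number of changed miRNAs was weighed against chance, GC content, scaling and other cells. Of the 35 ways to divide the 8 libraries into 4 and 4, only 1, the real one, called as many as 237. That share, 2.86%, is the smallest this count can give. It argues against chance only if any library could have stood in either group. The others, which mix the ages and so carry the age difference in their spread, called at most 0 by edgeR (at most 78 at an unadjusted p under 0.05). If the numbers pair the libraries, only the 8 that part all same-numbered pairs compare, the real one and 7 with at most 0 calls, too few for a share under 5%. With an offset that removes the trend on GC content of the hairpin side, 89.9% of the calls were kept in the same direction (91.6% with the replicate block). This argues against that GC content as the main source, while GC content of the sequenced insert was not measured. The listed erythroid, myeloid, endothelial and stromal miRNAs took at most 0.137% of any library's counts, while 17.6% of counts lay on other miRNAs in the other group. Other cells also hold miRNAs outside these lists, and no list was of B cells. This share therefore cannot decide how much other cells contributed. Scaling stays open, since 74.7% of the calls were kept with library totals and no added standard fixes the true level, so that a general shift and the directions of small changes cannot be told apart. Age, and whatever differs between the animals besides age, may account for the rest and was not separated by the design.

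Arm ratios were treated likewise. Only 1 of the 35 divisions, the real one, changed as many as 36 hairpins, with at most 0 by limma in the others (at most 20 at an unadjusted p under 0.05). This argues against chance on the same condition, while the 8 that part all pairs are too few. After the trend on the GC difference between the hairpin sides was removed, 88.9% of the hairpins were kept (91.7% with the replicate block).

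Of the erythroid, endothelial, stromal and liver miRNAs with enough counts to test, 8 were higher in neonatal libraries, by log2 fold changes from 0.97 for miR-451a to 2.08 for miR-122-5p (miR-486b-5p, with the sequence of miR-486a-5p, not counted). The median of the stromal list fell from 1.07 to 0.36 without a filter. The neonatal spleen is known to be a site of blood formation. GC content of the hairpin side is argued against, as 87.5% of the 8 were still higher with the GC offset. The exception, miR-143-3p, went from 1.07 ± 0.35 to 0.89 ± 0.38 (SE) and lost its call (edgeR's adjusted p = 0.0573). That shift was smaller than either SE, and with the replicate block added all 8 were still higher. A uniform dilution by other cells, which would raise the 8 alike, stays open. An exact permutation test of their profile centred per library gave p = 0.143, while Cochran's Q on the fitted errors, tried before it, gave p = 0.0104. The tests disagree on whether the 8 moved apart. The 8 were chosen after they were seen to be higher. The muscle and epithelial miRNAs, none of which passed as higher on the TMM scale, were left out, so both tests lean toward alike changes. More of particular other cells, which enrichment on CD8a should remove, could also account for the rise and stays open. All listed erythroid and myeloid miRNAs together took 0.0595 percentage points more of the counts (exact permutation p = 0.0286, the smallest possible, but 0.0571 without any one adult library and 0.125 within same-numbered pairs). With all listed endothelial and stromal ones added the difference was 0.0853 (exact permutation p = 0.0286). These shares are no separate support for other cells, since they mostly hold the miRNAs whose rise is to be explained. Of the 0.0741% in neonatal libraries, 0.0729% was erythroid and 0.00124% myeloid. No share was tested for liver miRNAs. Expression by the T cells themselves cannot be told apart from either, since the libraries hold no signal that separates the cells.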

How the results depend on the processing

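The alternatives with GC content, the largest precursor value, libraries numbered 1 and 3 or 2 and 4, and the share of erythroid and myeloid counts were chosen after seeing the data.

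The number of changed miRNAs stayed within 1.5 times of 237 in all alternatives run, from 213 (at least 10 CPM in 4 libraries) to 287 (no filter), and from 220 to 253 with a library left out. With library totals the split moved to 186 higher and 68 lower, which follows from the shift of 0.626, and let-7a-5p reversed to 0.199. let-7a-5p also lost its call with the GC offset, without a filter, and without adult library 3 (adjusted p by edgeR 0.0511) or neonatal library 2 (0.0632). Of the 237, RLE kept 95.8%, DESeq2 96.2% and limma-voom 99.2% in direction and call. Fits on the libraries numbered 1 and 3 and on those numbered 2 and 4 gave the same direction in both for all 234 of the calls tested in both. These calls came from the fit of the same libraries, mostly without overlap between groups. The shared direction was thus largely fixed in advance and is no separate support. Some miRNAs gained a call: miR-181a-5p passed with RLE (adjusted p = 0.0493), DESeq2 (0.0286), library totals, the GC offset with the replicate block (0.0392) and libraries 1 and 3 alone (0.041), and miR-92a-3p in libraries 1 and 3 (0.00602) and in 2 and 4 (0.0389); the cause was not tested. The number of hairpins with a changed arm ratio was 31 to 41 in all alternatives run.

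With the replicate block 265 miRNAs (125 higher, 140 lower) and 41 hairpins changed, and all of the 237 were kept. Among the lists and listed miRNAs it changed the calls of the miR-130 and miR-301 family, miR-92a-3p, miR-342-5p and miR-10a-5p, and no other.

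List calls were less steady than those of single miRNAs. In place of 5 lists, camera called 3 with RLE, 2 with totals, 11 without a filter, 6 with limma-voom, 2 with at least 10 CPM, 3 without the 10 most abundant miRNAs, 3 with the GC offset with or without the replicate block, 3 in libraries 2 and 4 alone, and 2 to 5 with a library left out. It called 0 with an estimated correlation, where fry called 16. The miR-29 and Sfmbt2 lists were called under all of these but the estimated correlation, and the cause was not tested for the others. camera was not run on DESeq2.

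The difference in erythroid and myeloid share was 0.0595 percentage points in the exact sign-flip test within pairs (replicate block), which cannot go below p = 0.125, and 0.0505 to 0.0717 with a library left out. Without any adult library p was 0.0571, as 2 of 35 divisions were as extreme, the other one placing neonatal library 4 with the adult libraries. Depth limits miRNAs near 3 counts per library, 1.15 to 2.34 CPM.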

Other observations

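The grouping of miRNAs by genomic position and the test of shared let-7 reads were chosen after the result was seen, and the GC test after the data but before its own result.

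miRNAs whose hairpins lie within 10000 bp of each other formed 28 clusters with at least 3 tested members, and 7 were called by camera, none with an estimated correlation (smallest adjusted p = 0.204 with an estimated correlation). On chromosome X, 7 of 8 miRNAs of the miR-322, miR-351, miR-450, miR-503 and miR-542 cluster (53047997 to 53054349) rose, with a median log2 fold change of 2.02 (camera adjusted p = 0.000473). miR-130b and miR-301b on chromosome 16 (17124061 to 17124496) rose on both arms, 4 of 4 (camera adjusted p = 0.00642), and so did 3 of 3 tested miRNAs of the miR-296 and miR-298 pair on chromosome 2 (174267047 to 174267585, camera adjusted p = 0.00642). Of the miR-106a to miR-363 cluster on chromosome X (52741693 to 52742567) 5 of 7 rose (camera adjusted p = 0.038). The let-7b and let-7c-2 hairpins on chromosome 15 (85706603 to 85707403) fell in 3 of 3 (camera adjusted p = 0.0379). However, let-7c-2-3p had almost the same levels as let-7a-1-3p of chromosome 13, so its reads may be shared, and the others are arms of let-7b. The 3 miRNAs of the miR-132 and miR-212 pair rose and the 3 of the miR-221 and miR-222 pair fell, without a camera call (adjusted p of 0.0529 and 0.0827).

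Some let-7 miRNAs and miRNAs from their clusters went apart. let-7a-5p and let-7c-5p fell while miR-99a-5p, miR-100-5p and miR-125b-5p, which lie beside a copy of let-7a or let-7c, rose, and the log2 ratio of the former to the latter, which does not depend on scaling, was 7.67 ± 0.19 (SD) in neonatal and 9.97 ± 0.23 in adult libraries. No p-value is given, since these members were chosen for the pattern. miR-99a-5p, miR-100-5p and miR-125b-5p, at 86.0, 81.4 and 130 CPM in neonatal libraries, are on the list of blood progenitor miRNAs. Of that list 3 rose and 2 fell, and whether other cells account for these rises was not tested. Reads shared between let-7 members stay open as an explanation. The median over 7 3p arms of let-7 hairpins was -1.12 (-0.5 with library totals), but let-7a-1-3p and let-7c-2-3p had almost the same counts, and the 3p arms of let-7a-2 and let-7c-1, the copies beside these miRNAs, had at most 2 counts in any library. GC content of the hairpin side is argued against, as 92.4% of the difference of -2.33 between the fitted changes was kept with the GC offset (91.2% with the replicate block). However, let-7a-5p alone went from -0.44 ± 0.12 to -0.11 ± 0.13 and lost its call. In another let-7 cluster, let-7e-5p, miR-99b-5p and miR-125a-5p on chromosome 17 (17830188 to 17830879) all fell, and their ratio moved the other way, from -1.44 ± 0.15 in adult to 0.21 ± 0.35 in neonatal libraries. A change in the other hairpins that also make let-7a and let-7c stays open.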
